A study of Arabidopsis thaliana with 17 samples.

How the data were processed

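Total RNA from whole rosettes of 42 days old Arabidopsis thaliana was measured on 17 Affymetrix arrays, 1 per plant sample. Per the labels' protocols, plants grew on compost with 10 h of light per day at 350 µmol/m2 s, 22 °C and 60% relative humidity, rosettes were frozen in liquid nitrogen, RNA was extracted with a column kit, and biotin-labelled cRNA was made from double-stranded cDNA. The labels gave 4 genotypes: the wild type Col-0 (n = 3), the abi4-102 mutant (n = 4), the vtc2 mutant (n = 4) and the abi4 vtc2 double mutant (n = 6). The labels call the samples of a genotype biological replicates. ABI4 encodes a transcription factor first known from abscisic acid insensitivity of seedlings, and VTC2 encodes an enzyme of ascorbate synthesis whose loss lowers leaf ascorbate.

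The values used were the intensities that the authors deposited, 1 per probe set and array, on a linear scale from 4.53 to 18087. How the authors computed these intensities, and how they normalized them between arrays, is not given in the sources used here. Array medians lay between 53.67 and 57.71 and array totals between 5741401 and 5955960. These near-equal medians and totals left no scaling step to be done, so the intensities were only put on the log2 scale, with no pseudocount because no value was 0 or below. For arrays, precision is limited by the number of arrays.

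The table held 22810 probe sets. The 64 control probe sets (Affymetrix AFFX controls) were left out of all tests of genes, which leaves 22746 probe sets tested. The array annotation gave exactly 1 gene to 13513 probe sets, several to 503 and none to 8730. Gene symbols were updated through a gene table of assembly TAIR10.1, which held the identifiers of 13436 of the 13513. The other 77 kept the annotation's name. Together they named 13356 loci. Unnamed probe sets entered the counts but no gene was named from them. No coordinates were used except the order of neighbouring loci in that gene table. ABI4, VTC2 and its near copy VTC5 had 0 annotated probe sets, so the transcripts of the mutated genes were not analysed here and the labels were not checked by them.

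Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 intensity, one coefficient per genotype, all 17 arrays, 13 residual and 4.24 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. The comparisons were abi4-102, vtc2 and the double mutant against Col-0, the double mutant against each single mutant, and the interaction of both mutations, which is the change of the double mutant less the sum of both single-mutant changes, all against Col-0. Genotypes, comparisons, tests, the alternatives not said to be added, 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule named, per comparison of 2 genotypes, the 10 largest rises and the 10 largest falls among probe sets past the threshold with exactly 1 gene and with no overlap between the arrays of both genotypes; for the interaction, the 10 lowest adjusted p-values; and up to 4 members with the lowest adjusted p per described list. Changes are given as log2 differences with the standard error (SE) of the fit.

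Of 440 loci in the 29 lists, 77 were named by the annotation and 363 were not named here. This left 7 lists with 4 or more probe sets (ascorbate synthesis, antioxidant enzymes, nuclear-encoded photosynthesis, anthocyanin and flavonoid synthesis, cold response, heat shock and cell wall expansion), 20 with 1 to 3 and 2 with none. For this reason 41 lists of 4 or more probe sets were added, by function or by shared symbol, after the annotation, the array summaries and the AFFX control values had been seen and before any test of a gene. Lists used 1 probe set per locus and were tested with camera (preset correlation 0.01, and again with an estimated correlation), which compares a list with the other genes, and with fry, which tests whether its members move one way on average. Adjustment was over 42 planned and 246 added list tests. Control signals were compared by exact permutation tests in R. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and for the placement of calls along the chromosomes (shuffles and Fisher's exact tests), and matplotlib 3.10.9 for the plots.

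The fit was tested on simulated arrays of the real probe sets with known changes before it was run on the real values. For abi4-102 against Col-0, 67.2% of changes of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold were recovered; for the double mutant against vtc2 these were 76.1%, 92.5% and 98.5%, and for the interaction 44.8%, 85.1% and 95.5%. False calls numbered 10 of 180 calls, 7 of 185 and 8 of 158 in these 3 comparisons. In each, 67, 67 and 66 probe sets were changed by 1.5-fold, 2-fold and 4-fold, far fewer than were called in the real comparisons. Recovery and false calls depend on how many probe sets change, so these numbers do not carry over to the real counts. Overlaps between comparisons that share arrays were set against 100 simulations of unchanged groups. Alternatives tried were quantile normalization, median centring, a filter on dim probe sets, only the arrays of the genotypes compared, an intensity trend with robust estimation, array weights, the replicate number as a block, 2 stricter thresholds, only probe sets with 1 unshared gene, and each of the 17 arrays left out in turn. Added after the control signals had been seen were a fit without 3 arrays whose control signals stood apart and fits with the hybridization controls or the 25S ribosomal RNA control as a covariate.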

Results

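Transcript levels in rosettes of a low-ascorbate mutant (vtc2), a mutant of the transcription factor gene ABI4 (abi4-102), their double mutant (abi4 vtc2) and the wild type Col-0 were compared on 17 arrays. There were 3 arrays of Col-0, 4 of abi4-102, 4 of vtc2 and 6 of abi4 vtc2. Median intensities were 53.67 to 56.19 in Col-0, 54.23 to 57.69 in abi4-102, 56.06 to 57.05 in vtc2 and 55.5 to 57.71 in the double mutant. Pearson correlations of log2 intensity across probe sets, which are not independent replicates, were 0.9853 to 0.9958 between arrays of a genotype and 0.9659 to 0.9926 between genotypes. The first principal component held 39.4% of the variance and set the 3 Col-0 arrays (-53.2 to -49.5) apart from all mutant arrays (-16.8 to 29.7). The second component held 11.6% and separated vtc2 (16.9 to 24.4) from abi4-102 (-20.4 to -16.8), with the double mutant between them (-8.3 to 0.1).

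**Figure D1:**
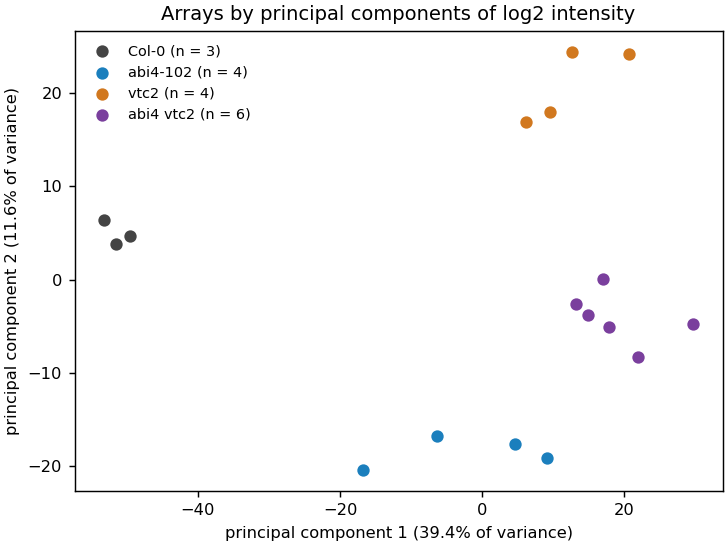
Each point is 1 of 17 arrays, placed by the first (39.4% of variance) and second (11.6%) principal component of log2 intensity and coloured by genotype. The 3 Col-0 arrays lie at -53.2 to -49.5 on the first component, and vtc2 and abi4-102 lie at opposite ends of the second.

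Control signals also differed between Col-0 and the mutants. The hybridization controls, which are added at the last step, averaged 0.44 log2 higher in the 3 Col-0 arrays than in the 14 mutant arrays (exact permutation test of 680 splits, two-sided, p = 0.00735, adjusted p = 0.022 over 10 control measures), and the 25S ribosomal RNA control 1.03 higher (exact p = 0.00588, adjusted p = 0.022). Actin and GAPDH controls were lower in Col-0 by 0.19 and 0.33 on the log2 scale (adjusted p = 0.022 each, same exact test). The unspiked tryptophan control was 0.09 higher in Col-0 (adjusted p = 0.0324, exact test), whereas ubiquitin, the poly-A spikes and the 3 ratios of 3' to 5' signal, a sign of RNA integrity, did not pass.

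The comparison of abi4-102 (n = 4) with Col-0 (n = 3) is that of the abi4 mutant with the wild type. The largest rises were in PDF1.2 (4.03 ± 0.81, 16.4-fold, limma adjusted p = 0.00176), AT2G44240 (4 ± 0.92, 16-fold) and PDF1.2b (3.82 ± 0.81, 14.2-fold), of which PDF1.2 and PDF1.2b are defensin genes of the jasmonate and ethylene defence pathway. PDF1.2b was measured by a probe set of the shared type, so its rise may not be separate from that of PDF1.2. AT3G47160 rose by 3.61 ± 0.21, AT1G56300 by 3.48 ± 0.21, AT2G39920 by 3.07 ± 0.14 and CHI (AT2G43570), a chitinase gene, by 2.87 ± 0.45, and AT4G16260, AT1G50290 and AT4G16146 rose by 2.41 to 2.59. The mean intensity of PDF1.2 was 70.9 ± 9.62 (SD) in Col-0 and 1620 ± 1560 in abi4-102. The largest falls were in AT3G28270 (-3.55 ± 0.62), QQS, a gene linked to starch content (-3.48 ± 0.92, adjusted p = 0.0125), AT3G44630 (-3.17 ± 0.80), CHIL, a chalcone isomerase-like gene of flavonoid synthesis (-2.96 ± 0.36, adjusted p = 2.18e-05), AT1G73490 (-2.85 ± 0.51) and BGLU47, a beta-glucosidase gene (-2.82 ± 0.57). AT2G27420, AT4G19500, AT1G62510 and AT4G08110 fell as well, by between 2.19 and 2.67 on the log2 scale.

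Among planned lists, 3 of 7 probe sets of anthocyanin and flavonoid synthesis fell (3 adjusted over the list alone), namely CHIL, UGT78D1 (-0.94 ± 0.13) and UGT78D2 (-0.96 ± 0.25). Their list mean was -1.10 (camera adjusted p = 0.015, and adjusted p = 0.693 with an estimated correlation), and leaving out Col-0 replicate 3 ended that call (camera adjusted p = 0.0776), as did the hybridization (0.0831) or 25S control (0.11) as a covariate. Of 6 ascorbate synthesis genes, 3 rose (3 adjusted over the list alone), AT4G33670 by 0.59 ± 0.08, PMM by 0.47 ± 0.11 and GLDH by 0.32 ± 0.08, while GME was at -0.27 ± 0.12 (adjusted p = 0.152). The ascorbate synthesis list passed in fry (adjusted p = 0.000477), which does not mean that every member rose. In camera, against the other genes, the list did not pass (adjusted p = 0.0847). Of 4 antioxidant enzyme genes, GR1, a glutathione reductase gene, fell by 0.84 ± 0.10 and SAPX, an ascorbate peroxidase gene, rose by 0.51 ± 0.10 (2 higher and 1 lower adjusted over the list alone). In cold response, 1 of 5 probe sets rose (COR15B, 0.87 ± 0.21) and 1 fell, in heat shock 1 of 4 rose (AT5G37670, 0.68 ± 0.09), and in cell wall expansion 2 of 8 rose (EXPA8, 0.88 ± 0.17, and EXPA4, 0.67 ± 0.16), with the same counts adjusted over the list alone and camera adjusted p = 0.563, 0.534 and 0.879. None of the 7 nuclear-encoded photosynthesis genes passed (0 adjusted over the list alone, camera adjusted p = 0.982). In the added pathogen defence list of 36 genes, 15 rose and 1 fell, among them AT1G13470 (2.01 ± 0.20), AT5G18470 (1.97 ± 0.39), PUB24, a ubiquitin ligase gene of immune signalling (1.03 ± 0.22), and EFR, the receptor gene for bacterial elongation factor (0.84 ± 0.11). The camera adjusted p of 6.75e-05 for this list became adjusted p = 0.662 with an estimated correlation.

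In total 4238 of 22746 probe sets changed, 2259 higher and 1979 lower, and 618 of them by 2-fold or more. For 3948 of the 4238 the arrays of both genotypes did not overlap, as 6270 of all probe sets did (27.6%, where chance gives 5.71%). The hybridization controls averaged 9.62 ± 0.14 (SD) in Col-0 and 9.25 ± 0.09 in abi4-102, and the 25S control 11.27 ± 0.39 and 9.70 ± 0.18. With these controls as covariates, added after they were seen, 2672 and 947 probe sets passed, while the changes kept most of their size (slopes of 0.92 and 0.89 on the reported changes). The hybridization controls ended the calls of AT2G44240, QQS and AT3G44630 among the 20 named genes, and the 25S control those of 11, these 3 with CHI, AT4G16260, AT3G28270, AT1G73490, BGLU47, AT2G27420, AT4G19500 and AT1G62510.

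The comparison of vtc2 (n = 4) with Col-0 (n = 3) is that of the low-ascorbate mutant with the wild type. AT1G56300 (3.44 ± 0.21), AT3G47160 (3.41 ± 0.21), CHI (3.20 ± 0.45, adjusted p = 4.51e-05) and AT2G39920 (3 ± 0.14) were again among the largest rises. They were joined by OSM34, an osmotin-like gene (3.11 ± 0.80, 8.61-fold, limma adjusted p = 0.00776), LUP5, an oxidosqualene cyclase gene (3.03 ± 0.49, adjusted p = 0.000151), AT4G16260 (2.78 ± 0.60), AT3G13950 (2.73 ± 0.35) and AT5G18470 (2.59 ± 0.39). AT2G44240 rose by 2.93 ± 0.92 (adjusted p = 0.0252), and leaving out any of 5 single arrays ended that call (adjusted p up to 0.0864, without vtc2 replicate 1). QQS fell by 3.75 ± 0.92 (adjusted p = 0.00571), AT2G27420 by 3.58 ± 0.42, with 1 vtc2 array at 5.17 log2 and the other 3 at 5.57 to 5.63, and AT1G62510, AT3G15310, CHIL and AT1G47400 fell by between 2.47 and 2.90. AT5G44050, AT5G66740, the transcription factor gene TINY2 and AT1G60590 changed by -2.35 to -2.07.

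Pathogen defence was the list with the most changes, with 26 of 36 genes higher and 0 lower. AT1G13470 rose by 2.39 ± 0.20, PUB24 by 1.83 ± 0.22, BIK1, an immune kinase gene, by 1.26 ± 0.16 and EFR by 0.87 ± 0.11. The list mean was 1.24 (camera adjusted p = 1.02e-12, and adjusted p = 0.614 with an estimated correlation). In the planned lists of few probe sets, the salicylic acid genes GRX480 (1.38 ± 0.35) and SAG101 (0.84 ± 0.15), the rapid stress genes STZ (1.95 ± 0.34) and CML38 (1.2 ± 0.37), and the senescence genes WRKY53 (2.57 ± 0.33) and WRKY6 (0.98 ± 0.29) rose. Of 14 endoplasmic reticulum stress genes 8 rose and 0 fell, with ATERDJ3B at 1.3 ± 0.23 and the calreticulin gene CRT1b at 1.19 ± 0.22, and of 10 autophagy genes 5 rose and 0 fell, with ATG8D at 1.34 ± 0.17. Their camera adjusted p values were 0.00235 and 0.000902, against adjusted p = 0.662 and 0.614 with an estimated correlation. Of 20 plastid-encoded photosystem genes 9 fell and 0 rose, among them psbN (-1.04 ± 0.19) and psbC (-0.75 ± 0.18), with camera adjusted p = 0.016 and adjusted p = 0.757 with an estimated correlation. That call ended without Col-0 replicate 3 (camera adjusted p = 0.104) or with the 25S control as covariate (0.0923), and the endoplasmic reticulum call with the hybridization controls as covariate (0.425).

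Of the planned lists, 3 of 7 anthocyanin and flavonoid genes fell (CHIL, UGT78D1 at -1.02 ± 0.13 and UGT78D2 at -0.94 ± 0.25, and 3 adjusted over the list alone), with camera adjusted p = 0.132. In ascorbate synthesis PMM (0.68 ± 0.11) and AT4G33670 (0.37 ± 0.08) rose, 2 higher and 1 lower adjusted over the list alone, with camera adjusted p = 0.498. All 4 antioxidant enzyme genes changed, 2 each way (the same adjusted over the list alone), with ATMDAR2, a monodehydroascorbate reductase gene, at 0.83 ± 0.11, SAPX at 0.29 ± 0.10, TAPX at -0.64 ± 0.11 and GR1 at -0.77 ± 0.10. In cold response COR15A (-1.55 ± 0.41), COR47 (-0.67 ± 0.20) and 1 probe set of several genes fell (1 higher and 3 lower adjusted over the list alone). PRK was the 1 photosynthesis gene of 7 that fell (-0.31 ± 0.09), AT5G37670 the 1 heat shock gene of 4 that rose (0.70 ± 0.09), and in cell wall expansion EXPA8 rose by 0.71 ± 0.17 and EXPB1 fell by 0.75 ± 0.23. These 3 lists had the same counts adjusted over the list alone, and no camera adjusted p below 0.397 was found for them, cold response or antioxidant enzymes.

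In total 5583 probe sets changed, 2767 higher and 2816 lower (49.6% higher, and 42% with median centring), with 1013 changed by 2-fold or more (655 higher and 358 lower). The arrays of both genotypes did not overlap for 5271 of them and for 33.1% of all probe sets (5.71% by chance). Hybridization controls were 8.97 ± 0.21 (SD) in vtc2 and the 25S control 10.42 ± 0.18, and with these as covariates 1808 and 3543 probe sets passed, with slopes of 0.84 and 0.94 on the reported changes. The hybridization controls ended the calls of 7 of the 20 named genes, OSM34, LUP5, AT2G44240, AT4G16260, AT5G18470, QQS and AT1G62510, and the 25S control those of AT2G44240 and QQS.

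The double mutant (n = 6) against Col-0 (n = 3) had the largest count, 6879 probe sets changed with 3652 higher and 3227 lower (53.1% higher), of which 1098 changed by 2-fold or more (651 higher and 447 lower). With median centring 3066 were higher and 3904 lower (44% higher). AT3G47160 rose by 3.81 ± 0.19, AT1G56300 by 3.76 ± 0.20, CHI by 3.75 ± 0.42 (limma adjusted p = 2.63e-06), AT2G39920 by 3.36 ± 0.13 and AT5G18470 by 3.12 ± 0.36. PDF1.2 rose by 3.77 ± 0.75 (adjusted p = 0.000812), although double-mutant replicate 3 stood at 6.89 and the other 5 at 10.04 to 10.97. AT3G13610, a gene of scopoletin synthesis, rose by 3.07 ± 0.36 (8.39-fold), and AT2G44240, AT4G16146 and AT1G78410 by 2.98 to 3.63. The lowest were QQS (-5.06 ± 0.85, 33.4-fold lower), AT1G76960 (-4.38 ± 0.85), AT2G27420 (-4.04 ± 0.39) and AT1G73490 (-3.88 ± 0.47, adjusted p = 6.12e-06). AT3G28270, AT3G44630, AT1G69523, AT1G62510, CHIL and AT1G69160 changed by -2.81 to -2.40.

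In the double mutant 27 of 36 pathogen defence genes rose and 1 fell, with AT1G13470 at 2.25 ± 0.19 and PUB24 at 1.71 ± 0.20 (camera adjusted p = 8.63e-10, and adjusted p = 0.614 with an estimated correlation). Endoplasmic reticulum stress (7 of 14 higher, ATERDJ3B 1.58 ± 0.21) and autophagy (6 of 10 higher, ATG8D 1.53 ± 0.16) rose with none lower, with camera adjusted p = 0.00706 and 0.0141, each adjusted p = 0.662 with an estimated correlation. Of plastid-encoded photosystem genes 5 of 20 fell, psbC by 0.94 ± 0.17 and psbZ by 0.69 ± 0.11 (camera adjusted p = 0.0284, adjusted p = 0.764 with an estimated correlation). The photosystem call ended with quantile normalization (camera adjusted p = 0.0504), median centring (0.0507) or the filter on dim probe sets (0.0631) and without Col-0 replicate 3 (0.151) or double-mutant replicate 3 (0.0894), and the autophagy call with that filter (0.0631) or without Col-0 replicate 2 (0.0511). With the hybridization controls as covariate the endoplasmic reticulum (0.0933) and autophagy (0.0724) calls ended, and with the 25S control the photosystem call (0.153). In the planned lists, 3 of 7 photosynthesis genes fell, LHCB4.3, a minor antenna gene, by 1.12 ± 0.11, PRK by 0.50 ± 0.08 and RCA by 0.21 ± 0.06 (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.225). The same 3 flavonoid genes fell as in the single mutants (3 adjusted over the list alone, UGT78D1 -1.16 ± 0.12, camera adjusted p = 0.358), and AT4G33670 (0.56 ± 0.08), PMM (0.69 ± 0.10) and GLDH (0.37 ± 0.07) rose in ascorbate synthesis (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.174). ATMDAR2 (0.79 ± 0.11) and SAPX (0.52 ± 0.09) rose and GR1 (-0.98 ± 0.09) and TAPX (-0.56 ± 0.11) fell, while COR15B rose (1.12 ± 0.19) and COR15A (-1.25 ± 0.38) and COR47 (-0.71 ± 0.19) fell. EXPA8 (0.85 ± 0.16) and EXPA4 (0.55 ± 0.14) rose among 8 cell wall expansion genes and AT5G37670 (0.79 ± 0.08) among 4 heat shock genes (the same adjusted over the list alone, camera adjusted p = 0.397 and 0.498). WRKY53 (2.48 ± 0.31) and the clock gene GI (1.44 ± 0.15) rose, as both did in abi4-102 (1.48 ± 0.33 and 1.13 ± 0.16) and in vtc2 (2.57 ± 0.33 and 1.15 ± 0.16).

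Arrays of both genotypes did not overlap for 5687 of the 6879 changed probe sets and for 27.6% of all (2.38% by chance). Hybridization controls were 9.30 ± 0.26 (SD) in the double mutant and the 25S control 10.50 ± 0.59. Among the 20 named genes the hybridization controls as covariate ended the calls of AT2G44240 and AT3G44630, and the 25S control that of AT3G44630.

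**Figure D2:**
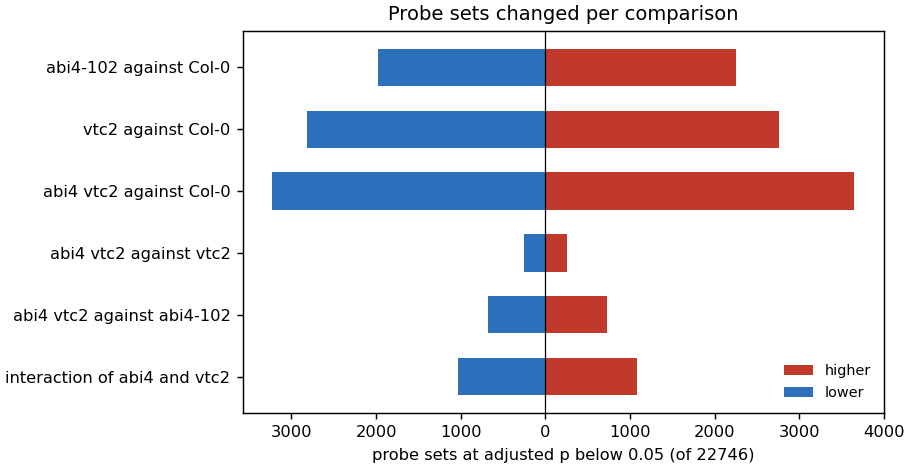
Bars give the number of probe sets past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left, of 22746 tested. Counts against Col-0 were 4238 to 6879, and counts between the double and the single mutants were 515 and 1412.

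Marker genes of other cell types changed in several comparisons. TRY, a trichome gene, fell in abi4-102 (-0.92 ± 0.15), vtc2 (-0.88 ± 0.15) and the double mutant (-1.46 ± 0.14) against Col-0, and FMA, a guard cell gene, fell in all 3 (-0.52 ± 0.12, -0.55 ± 0.12 and -0.49 ± 0.11). SWEET11, a phloem gene, fell in vtc2 (-0.70 ± 0.21, limma adjusted p = 0.0192). Of the flowering genes, AGL24 fell in abi4-102 (-0.66 ± 0.16) and AGL42 in vtc2 (-1.52 ± 0.42), and both fell in the double mutant (-0.57 ± 0.15 and -1.85 ± 0.39). Leaving out Col-0 replicate 1 ended the call of AGL42 in vtc2. The root gene PYK10 was at -1.92 ± 1.18, 0.77 ± 1.18 and 0.23 ± 1.09 and the dividing cell gene AUR1 at -0.11 ± 0.15, -0.27 ± 0.15 and -0.13 ± 0.14 in the same 3 comparisons, and neither passed.

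The single mutants shared many of their calls against Col-0, 73.4% of those of abi4-102 and 55.7% of those of vtc2. Of their calls 1622 were higher and 1487 lower in both, and 11 went opposite ways, where independent lists would give 274.8, 245 and 520.4. CHI, AT3G47160, AT1G56300 and AT2G39920 were among those higher in both, and QQS, CHIL, AT2G27420 and AT1G62510 among those lower. In all 3 mutants 1582 probe sets were higher and 1412 lower. Unchanged groups were simulated by shuffling the deviations of all 17 arrays from their genotype means, with 1 control group shared by both changes. They gave a correlation of log2 changes across probe sets of 0.56 (0.083 to 0.866), a range that holds the 0.786 of the data. The covariance was 0.1366 against 0.0156 (0.0013 to 0.0327) simulated, a difference of 0.121. The 3 Col-0 arrays could not be divided into parts of at least 2, so the part of the excess that comes from these shared controls was not separated. Of the 3109 calls shared in direction, 1313 were left with the hybridization controls as covariate and 760 with the 25S control.

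The comparison of the double mutant (n = 6) with vtc2 (n = 4) sets plants with both mutations against plants with the vtc2 mutation alone. AT1G76960 changed most, by -6.46 ± 0.78 (limma adjusted p = 0.000187), from a mean intensity of 2260 ± 509 (SD) in vtc2 to 26.9 ± 9.92. AT1G73490 fell by 3.78 ± 0.43, the cytochrome P450 genes CYP71B24 and CYP71B26 by 2.73 ± 0.33 and 2.22 ± 0.31, AT1G69550 by 2.21 ± 0.18, ORA47, a jasmonate-responsive transcription factor gene, by 1.84 ± 0.17 (3.57-fold, adjusted p = 1.1e-05), AT1G80960 by 1.83 ± 0.18 and AT1G72060 by 1.59 ± 0.17. The largest rises were AT1G02300 (1.56 ± 0.20), AT2G16000 (1.52 ± 0.15), AT2G20460 (1.5 ± 0.13), AT2G19840 (1.19 ± 0.11) and SPI, a BEACH-domain gene (1.18 ± 0.09), for which double-mutant replicate 6 stood at 7.36 and the other 5 at 6.79 to 6.98. A further 7 of the 20 named genes lost their call when 1 array was left out. These were SUFE2 (1.41 ± 0.28, adjusted p = 0.0578 without vtc2 replicate 4), CYTC6A (1.4 ± 0.29, adjusted p = 0.0649 without vtc2 replicate 1), PRX52 (1.19 ± 0.28, 8 arrays), AT5G38260 (1.06 ± 0.24, 4 arrays), AT2G29500 (1.04 ± 0.23, 4 arrays), AT3G48080 (-2.58 ± 0.62, 7 arrays) and AT5G44580 (-1.76 ± 0.45, 13 arrays), where the highest adjusted p was 0.0997, 0.0832, 0.105, 0.108 and 0.146 for the last 5. The fit without 3 arrays of unusual control signals ended the same 7 calls, the hybridization controls as covariate those of CYTC6A, PRX52, AT5G38260, AT2G29500 and AT5G44580, and the 25S control that of AT5G44580.

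Changes of lists were few here. Of 7 photosynthesis genes LHCB4.3 alone fell (-0.93 ± 0.10, 1 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.255 with an estimated correlation). Of 8 cell wall expansion genes EXPA4 alone rose (0.65 ± 0.13, 1 adjusted over the list alone, camera adjusted p = 0.0194, and adjusted p = 0.255 with an estimated correlation), a call that ended without vtc2 replicate 1 (camera adjusted p = 0.066) or double-mutant replicate 4 (0.059) and with the hybridization controls as covariate (0.285). Pathogen defence had 0 higher and 1 lower of 36 (camera adjusted p = 0.444), and the trichome gene TRY fell by 0.59 ± 0.13. No member of ascorbate synthesis, antioxidant enzymes, anthocyanin and flavonoid synthesis, cold response or heat shock passed over all probe sets, where adjusted over the list alone 3 ascorbate synthesis genes, 1 cold response gene and 1 antioxidant gene were higher and 1 antioxidant gene lower. In total 515 probe sets changed, 262 higher and 253 lower, 76 by 2-fold or more, and 3376 had an unadjusted p under 0.05. Arrays did not overlap for 416 of the 515 and for 4.4% of all probe sets (0.95% by chance), and leaving out vtc2 replicate 1, 3 or 4 gave 268, 324 or 207 calls. Only the arrays of both genotypes gave 335, the fit without 3 arrays of unusual control signals 174 and the hybridization controls as covariate 221.

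**Figure D3:**
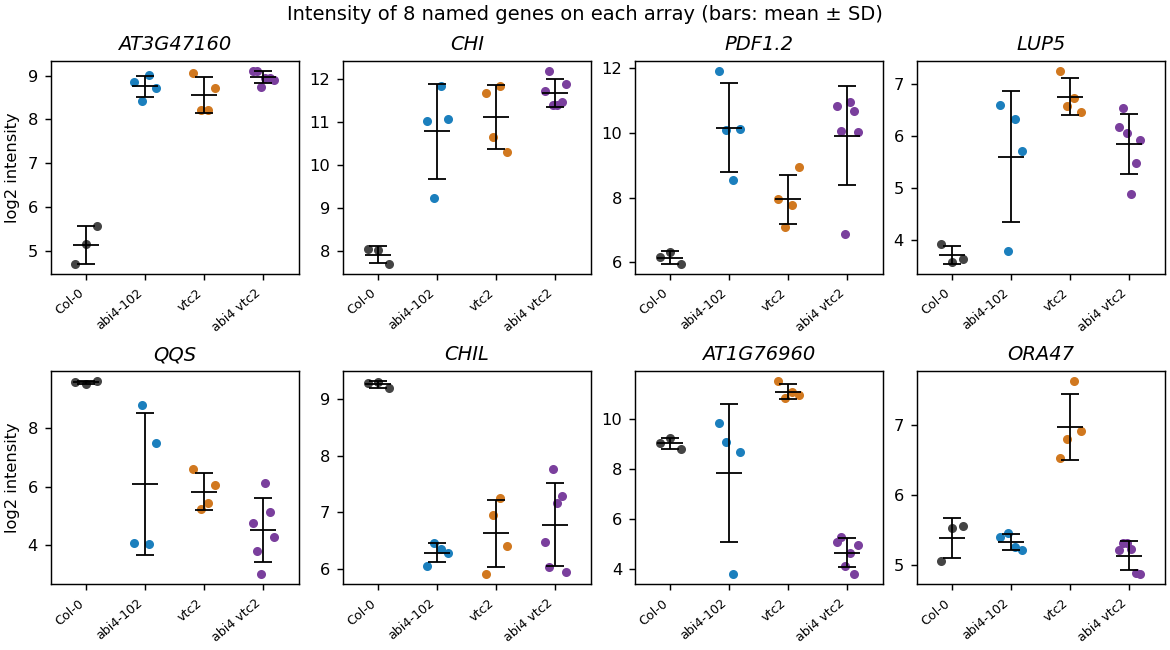
Points are the log2 intensity of 8 named genes on each of 17 arrays, with bars at the mean and standard deviation of each genotype. AT3G47160, CHI, QQS and CHIL part Col-0 from all mutants, whereas AT1G76960 fell by 6.46 and ORA47 by 1.84 from vtc2 to abi4 vtc2.

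Of the probe sets changed in vtc2 against Col-0, 126 changed the opposite way in the double mutant against vtc2, 76 of them raised in vtc2 and 50 lowered, and 100 changed the same way in both (54 higher and 46 lower). Independent lists would give 63.2 opposite calls and, in the same direction, 31.9 higher and 31.3 lower, so that calls of both kinds were above these numbers. ORA47 rose by 1.59 in vtc2 and fell by 1.84 in the double mutant, AT1G72060 rose by 1.54 and fell by 1.59, AT1G62760 rose by 1.46 and fell by 1.41, and SPI fell by 1.05 and rose by 1.18. Across all probe sets the correlation of both changes was -0.139, where the shared vtc2 arrays alone gave -0.504 (-0.765 to -0.125) in simulation, and the covariance was -0.014 against -0.0117 (-0.0263 to -0.002). The covariance lies inside its simulated range, so it shows no reversal across all probe sets beyond that of the shared arrays. The correlation lies inside as well, but the simulated groups held no change of vtc2, so its range decides nothing. These groups had at most 1 opposite call (mean 0.01), and without changes they cannot say how many opposite calls real changes would give. Leaving out vtc2 replicate 1 or 4 gave 61 or 49 probe sets changed opposite ways. The fit without 3 arrays of unusual control signals gave 52 and the hybridization controls as covariate 45.

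The comparison of the double mutant (n = 6) with abi4-102 (n = 4) sets plants with both mutations against plants with the abi4 mutation alone. AT4G19500 (2.33 ± 0.37, limma adjusted p = 0.00129), AT3G60450 (2.19 ± 0.12), AT3G13610 of scopoletin synthesis (2.05 ± 0.33, 4.13-fold), AT4G20480 (1.91 ± 0.23), AT4G36520 (1.81 ± 0.21) and AT4G16870 (1.73 ± 0.14) rose, with AT5G50310 (1.71 ± 0.11), AT4G02540 (1.63 ± 0.07) and AT4G08110 (1.46 ± 0.14). AT3G28510 rose by 2.34 ± 0.50, and that call ended without abi4-102 replicate 2 (adjusted p = 0.054). AT4G19430 fell by 2.86 ± 0.38, AT1G78450 by 1.82 ± 0.25, AGL42 by 1.67 ± 0.35 and AT3G28500 by 1.57 ± 0.23. AT4G19240, AT2G16750, AT2G07777, AT4G22280 and AT3G55940 changed by -1.48 to -1.14. AT5G56380 was at -1.59 ± 0.46 with an adjusted p of 0.0498, which leaving out any of 15 single arrays moved past the threshold (up to 0.127, without abi4-102 replicate 2).

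Of the 36 pathogen defence genes 10 rose and 0 fell, among them UGT76B1 (2.00 ± 0.47), AT1G57630 (1.35 ± 0.23), AT1G21520 (1.26 ± 0.23) and GRX480 (1.21 ± 0.30). The camera adjusted p was 6.06e-09, and adjusted p = 0.614 with an estimated correlation. Of 14 endoplasmic reticulum stress genes ATERDJ3B (0.73 ± 0.19) and DER2.1 (0.43 ± 0.12) rose (camera adjusted p = 0.00706, and adjusted p = 0.662 with an estimated correlation). Of 7 photosynthesis genes LHCB4.3 (-1.09 ± 0.10) and PRK (-0.28 ± 0.07) fell (2 adjusted over the list alone, camera adjusted p = 0.00798, and adjusted p = 0.255 with an estimated correlation). ATMDAR2 rose by 0.49 ± 0.10 and TAPX fell by 0.44 ± 0.10 among 4 antioxidant enzyme genes (the same adjusted over the list alone). No member of ascorbate synthesis, anthocyanin and flavonoid synthesis, cold response, heat shock or cell wall expansion passed over all probe sets, and adjusted over the list alone 2 cell wall expansion genes were higher. WRKY53 rose by 1 ± 0.28 and TRY fell by 0.54 ± 0.13. In total 1412 probe sets changed, 733 higher and 679 lower (51.9% higher), and with median centring 571 were higher and 899 lower (38.8% higher). There were 125 changes of 2-fold or more, 90 higher and 35 lower, and arrays did not overlap for 954 of the 1412 and for 6.3% of all probe sets (0.95% by chance). Leaving out abi4-102 replicate 2 or 4 or double-mutant replicate 2 gave 497, 608 or 918 calls. Only the arrays of both genotypes gave 826, array weights 2447, the fit without 3 arrays of unusual control signals 790 and the 25S control as covariate 819. That covariate ended the calls of AT3G28510, AGL42 and AT5G56380, and the fit without the 3 arrays that of AT5G56380.

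**Figure D4:**
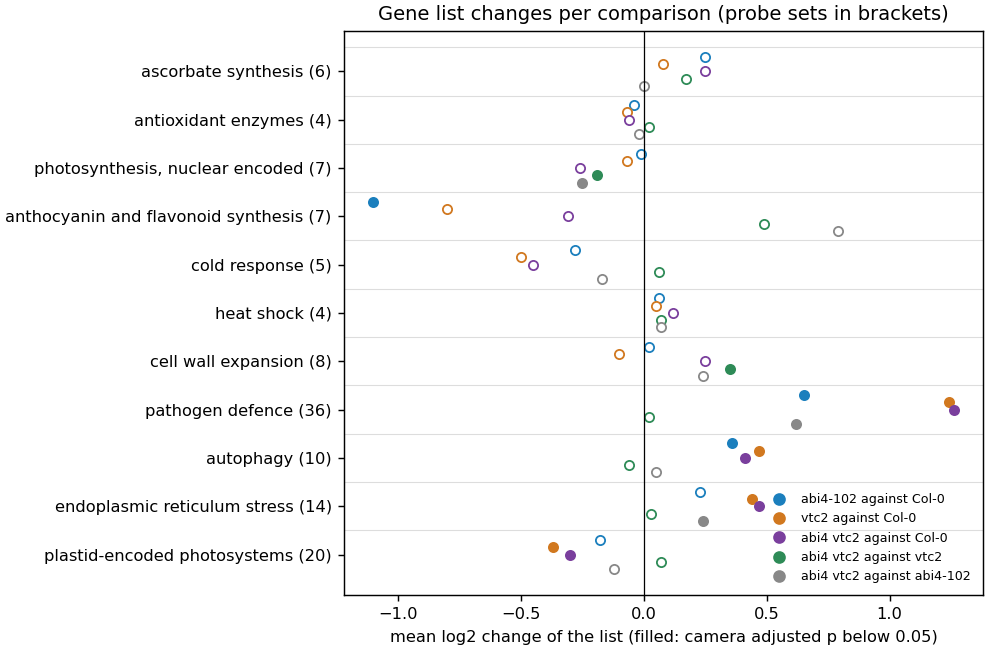
Points give the mean log2 change of 11 gene lists in 5 comparisons, filled where the camera adjusted p was below 0.05 with the preset correlation of 0.01. Pathogen defence reached 1.24 in vtc2 and 1.26 in abi4 vtc2 against Col-0, and no filled point kept an adjusted p below 0.05 with an estimated correlation.

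The interaction asks whether the double mutant differed from the sum of both single-mutant changes. The 10 lowest adjusted p-values were in AT4G02540 (1.79 ± 0.11, limma adjusted p = 3.99e-08), AT4G30660 (-1.97 ± 0.13), AT2G39920 (-2.72 ± 0.19), DPE1, a starch breakdown gene (-1.97 ± 0.16), AT5G50310 (2.05 ± 0.17), PORB, a chlorophyll synthesis gene (-1.85 ± 0.15), AT1G70820 (-1.36 ± 0.11), BGLU44, a beta-glucosidase gene (-2.24 ± 0.18), AT3G47160 (-3.20 ± 0.27) and AT5G66740 (1.84 ± 0.16). Single arrays stood away from the rest of their genotype for AT4G30660 (abi4-102 replicate 1, 10.15) and AT5G50310 (vtc2 replicate 1, 6.72). In anthocyanin and flavonoid synthesis 3 of 7 genes had a positive interaction (3 adjusted over the list alone), CHIL at 3.11 ± 0.48, UGT78D2 at 1.22 ± 0.33 and UGT78D1 at 0.80 ± 0.18 (camera adjusted p = 0.00798, and adjusted p = 0.618 with an estimated correlation). In pathogen defence 9 of 36 had a negative one, with AT1G13470 at -2.15 ± 0.26 and EFR at -0.73 ± 0.14, and in autophagy 3 of 10, with ATG8D at -0.95 ± 0.22. Their camera adjusted p values were 3.56e-06 and 0.000748, against adjusted p = 0.662 and 0.614 with an estimated correlation. With the hybridization controls as covariate all 3 list calls ended (0.0831 for flavonoid synthesis, 0.181 for pathogen defence and 0.0768 for autophagy). GR1 (0.62 ± 0.13) among antioxidant enzymes was positive, and AT4G33670 (-0.40 ± 0.11) and PMM (-0.47 ± 0.14) in ascorbate synthesis and GI (-0.83 ± 0.21) were negative.

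In total 2109 probe sets passed, 1078 positive and 1031 negative, and 580 reached 2-fold. Of these, 2057 (97.5%) had a sign opposite to both single-mutant changes, and across all probe sets the interaction correlated with the summed single-mutant changes at -0.889. Simulated unchanged groups had 96.3% (77.8 to 99.9%) over as many probe sets with the lowest p and a correlation of -0.861 (-0.948 to -0.655). Both values of the data lie inside these ranges, so neither tells an interaction from arrays that enter with opposite sign. The simulated groups held no changes, so they do not show why 2109 probe sets passed. Of the 2109, 1626 were called in the same direction in all 3 mutants against Col-0. With the hybridization or 25S controls as a covariate 418 and 296 probe sets passed.

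**Figure D5:**
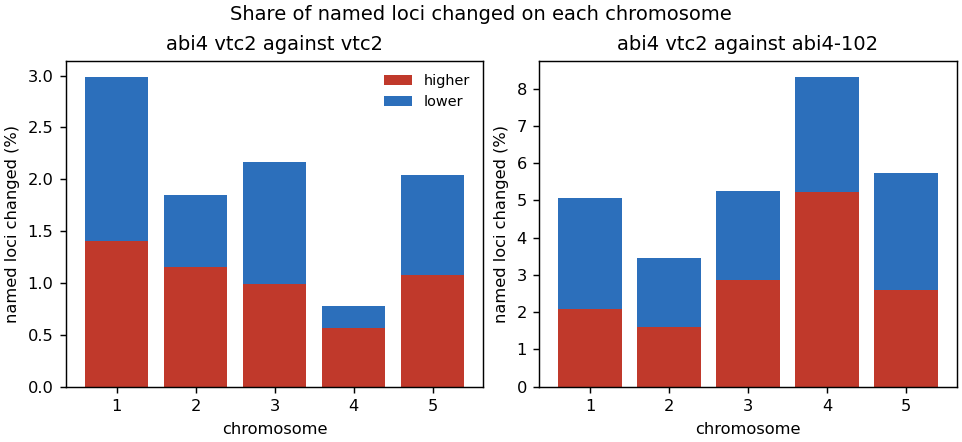
Stacked bars give the percent of named loci changed on chromosomes 1 to 5, higher and lower, for the double mutant against vtc2 and against abi4-102. Against vtc2 0.8% of the loci on chromosome 4 changed, and against abi4-102 8.3% did.

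Calls were not spread evenly over the chromosomes. Against vtc2, 0.8% of the named loci on chromosome 4 changed and 2.3% of those on other chromosomes (Fisher's exact test, odds ratio 0.33, adjusted p = 2.02e-05 over 25 tests), and 3.0% on chromosome 1 against 1.8% elsewhere (adjusted p = 0.000322). Against abi4-102, 8.3% changed on chromosome 4 and 5.0% elsewhere (odds ratio 1.73, adjusted p = 3.84e-07), and 3.5% on chromosome 2 against 5.9% elsewhere (odds ratio 0.57, adjusted p = 2.02e-05). Calls against Col-0 were uneven too, with more on chromosome 4 in abi4-102 (odds ratio 1.21, adjusted p = 0.00743, Fisher's exact test), more on chromosome 1 in vtc2 (1.13, adjusted p = 0.0259) and the double mutant (1.14, adjusted p = 0.0112), and fewer on chromosome 2 in abi4-102, vtc2 and the double mutant (0.81, 0.83 and 0.84). VTC2 lies on chromosome 4 and ABI4 on chromosome 2. Neighbouring loci are not independent, so these p-values are too small where changes of neighbours go together.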

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

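Chosen only after the result was seen were the covariate tests of the single mutants alone and the test of a change that both mutations share; the fits with control signals as covariates were added after those signals were seen.

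Of 225 groups of 1 named gene in 1 genotype, 8 held an array far from the others by Dixon's test, which chance gives in about 1 of 20 groups. Col-0, with 3 arrays, was too small for this test and was left out of it, for genes and control signals alike. In log2 intensity these were PDF1.2 in double-mutant replicate 3 (6.89, others 10.04 to 10.97), AT1G50290 in the same array (5.39, others 7.13 to 8.06), AT2G27420 in vtc2 replicate 2 (5.17, others 5.57 to 5.63), PRX52 in vtc2 replicate 2 (3.88, others 4.77 to 4.92), SPI in double-mutant replicate 6 (7.36, others 6.79 to 6.98), AT5G44580 in abi4-102 replicate 1 (8.47, others 10.60 to 10.74), AT5G50310 in vtc2 replicate 1 (6.72, others 7.20 to 7.24) and AT4G30660 in abi4-102 replicate 1 (10.15, others 10.53 to 10.54). Of 30 groups of 1 control signal in 1 genotype, 4 held such an array. These were the poly-A spikes in double-mutant replicate 2 (3.50, others 6.10 to 7.21), the unspiked tryptophan control in abi4-102 replicate 1 (2.96, others 2.87 to 2.88), the actin 3' less 5' signal in vtc2 replicate 2 (3.41, others 3.34) and the ubiquitin 3' less 5' signal in double-mutant replicate 4 (1.72, others 1.54 to 1.57). In the control probe sets, which the comparisons of genes do not use, actin averaged 10.91 and GAPDH 11.52 in vtc2, above every Col-0 array (highest 10.83 and 11.24).

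The interaction term passed for 2109 probe sets and for 42 named genes, and with the hybridization or 25S controls as covariate for 418 and 296 probe sets. As the Col-0 arrays enter it with the sign opposite to that in the single-mutant changes, a batch of Col-0 arrays would give such terms as well. Among genes raised against Col-0 in a single mutant it was -3.20 for AT3G47160, -3.17 for AT1G56300, -2.72 for AT2G39920, -2.31 for CHI, -2.73 for AT4G16260, -1.72 for AT4G16146, -2.79 for LUP5 and -2.23 for AT3G13950. Among genes lowered there it was 3.11 for CHIL, 2.88 for BGLU47, 2.22 for AT2G27420, 2.58 for AT4G19500, 2.71 for AT1G62510, 2.32 for AT4G08110, 1.89 for AT3G15310, 2.66 for AT1G47400, 2.21 for AT5G44050, 1.84 for AT5G66740, 1.64 for TINY2 and 1.42 for AT1G60590. Among genes named from the other comparisons it was -1.52 for AT1G78410, -5.28 for AT1G76960, 1.13 for AT1G69160, 1.12 for SPI, -1.79 for ORA47, -1.08 for AT1G80960, -1.14 for AT1G72060, 1.01 for AT3G60450, 1.88 for AT4G20480, 1.47 for AT4G36520, 0.90 for AT4G16870, -1.45 for AT3G28500, -1.35 for AT4G19240, -1.43 for AT2G07777 and -1.27 for AT4G22280. Those with the lowest adjusted p were 2.05 for AT5G50310, 1.79 for AT4G02540, -1.97 for AT4G30660, -1.97 for DPE1, -1.85 for PORB, -1.36 for AT1G70820 and -2.24 for BGLU44.

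The 3 Col-0 arrays stood apart from the arrays of all 3 mutants. Hybridization efficiency and the share of ribosomal RNA stay open as causes in all 3 mutants. In the double mutant, changes with these controls as a covariate had slopes of 0.94 and 0.96 on the reported ones. The control ranges there were 9.03 to 9.72 against 9.52 to 9.78 in Col-0, and 9.81 to 11.41 against 11.01 to 11.72. Only double-mutant replicate 4 (9.72 and 11.41) reached the Col-0 range. That array is among the 3 of unusual control signals, so slopes that rest on its overlap cannot decide. Arrays of the single mutants did not overlap those of Col-0 in either control, so there a covariate cannot part these controls from the genotype. For hybridization the slopes were 0.92 in abi4-102 and 0.84 in vtc2, with 58.2% and 30.7% of calls kept. For ribosomal RNA they were 0.89 and 0.94, with 20.4% and 59.9% kept. The authors' normalization was left open too. Quantile normalization of arrays with near-equal medians left the changes as they were (6964 calls in the double mutant, slope 1) and so tests nothing. Harvest at another time of day also stays open, since 0 of 6 changes of the evening genes COR27 and AT4G33980 passed as rises (log2 -0.14 to 0.05) while GI rose in all 3 mutants. A change that both mutations share would give the excess covariance of 0.121, but a batch of Col-0 plants or arrays would give it as well, and with 1 set of 3 Col-0 arrays they cannot be told apart.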

How the results depend on the processing

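Chosen only after the data were seen were the fit without 3 arrays of unusual control signals (vtc2 replicate 1, double-mutant replicates 2 and 4) and the fits with a control signal as covariate. Over the planned and added fits, of 17407 values of named genes and list members 15739 kept their side of the threshold, 1667 lost it and 1 turned, psbN in abi4-102 against Col-0 (-0.77 reported, 0.13 with the 25S control as covariate). Of 7986 list means 7696 stayed the same, 69 lost their call, 74 gained one with the reported sign and 147 moved, and no called list turned. An uncalled list that passed with the other sign was counted as the same or as moved. Of 626 changes of genes, the hybridization covariate ended 243 calls, the 25S covariate 260 and the fit without the 3 arrays 111. Quantile normalization, median centring, the filter on dim probe sets and the intensity trend kept every count within 1.5 times, but median centring turned the split of the double mutant against abi4-102 to 571 higher and 899 lower and against Col-0 to 3066 and 3904, and made that of vtc2 against Col-0 2454 and 3393. Counts are given for abi4-102, vtc2 and the double mutant against Col-0, the double against vtc2, the double against abi4-102, the interaction, the overlap of the single mutants and the reversal of vtc2 calls, in this order. At 2-fold or more they were 618, 1013, 1098, 76, 125, 580, 444 and 15, and with 1 unshared gene per probe set 2177, 2919, 3616, 283, 699, 1036, 1566 and 70, where the stricter rule and the fewer probe sets tested lower them by construction. At an adjusted p below 0.01 they were 2527 and 3626 for the single mutants, then 142, 419, 998, 1875 and 30 for the last 5. For the settings that follow the cause was not tested. With only the arrays compared, 335 probe sets changed against vtc2 and 826 against abi4-102, and with array weights 2447 against abi4-102. Without the 3 arrays there were 174, 790 and, for the reversal, 52. With hybridization controls as covariate the counts were 2672 for abi4-102, 1808 for vtc2, 221 for the double against vtc2, 418 for the interaction, 1313 for the overlap and 45 for the reversal, and with the 25S control 947, 3543, 819 against abi4-102, 296 for the interaction and 760 for the overlap. Of 42 planned list tests 5 passed, and 0 with an estimated correlation. Leaving out each array in turn gave 3125 to 4424, 4551 to 5784, 5655 to 6944, 207 to 592, 497 to 1577, 1608 to 2153, 2340 to 3262 and 49 to 153. Against vtc2 the count was 268, 324 and 207 without vtc2 replicates 1, 3 and 4, against abi4-102 it was 497 and 608 without abi4-102 replicates 2 and 4 and 918 without double-mutant replicate 2, and the reversal was 61 and 49 without vtc2 replicates 1 and 4. With the replicate number as a block the counts were 3836, 5237, 6190, 237, 961, 1515, 2886 and 56, where the 237 against vtc2 were 98 higher and 139 lower. Of 21 pairs of arrays with the same number in different genotypes 6 correlated above 0.1 (-0.236 to 0.21). Their mean correlation was 0.014, beside -0.003 for pairs of other numbers, which shows little pairing. As 7 of 15 arrays correlated best with their own number, a count for which no chance level was computed, a pairing is not excluded. The dimmest signals, near the lowest intensity of 4.53, limit what can be seen of weakly expressed genes.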

Other observations

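Chosen only after the result was seen were the tests of random placement, the shares of chromosomes 2 and 4, the comparison of parental splits inside and outside the fullest windows, and the overlaps between comparisons that share no arrays.

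Members of further gene groups changed against Col-0. In the TBL family of cell wall acetylation 6 of 22 genes fell in abi4-102, 9 in vtc2 and 9 in the double mutant, where 1 rose, with TBL37 at -1.29 ± 0.13, -1.02 ± 0.13 and -0.81 ± 0.12 and TBL26 at -1.15 ± 0.21, -1.45 ± 0.21 and -1.31 ± 0.19 (camera adjusted p = 0.00787, 0.016 and 0.0121, each adjusted p = 0.614 with an estimated correlation). The filter on dim probe sets ended the calls in vtc2 (camera adjusted p = 0.0631) and the double mutant (0.0578), and the hybridization controls as covariate in all 3 (0.0548, 0.0933 and 0.0548). Of 15 genes grouped by the symbol TRM alone, 6 fell in the double mutant and 0 rose, with TRM18 at -0.54 ± 0.09 and TRM20 at -0.60 ± 0.11 (camera adjusted p = 0.0221, adjusted p = 0.614 with an estimated correlation, and camera adjusted p = 0.0632 with that filter, 0.0548 with that covariate and 0.0516 without the 3 arrays of unusual control signals). Of 11 iron supply genes 3 fell in each mutant and 1 rose in the double mutant. BHLH101 was at -1.24 ± 0.16, -1.29 ± 0.16 and -1.25 ± 0.15 and PYE at -0.96 ± 0.15, -0.98 ± 0.15 and -1.14 ± 0.14, while the list did not pass (camera adjusted p = 0.198, 0.198 and 0.311).

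Of 17 jasmonate-linked genes 2, 3 and 3 rose and 3 fell in each mutant, with JMT at -1.17 ± 0.16, -1.41 ± 0.16 and -1.58 ± 0.15 and MYC4 at -0.68 ± 0.14, -0.97 ± 0.14 and -1.06 ± 0.13 (camera adjusted p = 0.444, 0.891 and 0.737). Of 10 VPS genes of vesicle sorting 3, 4 and 5 rose and 0, 1 and 1 fell, with VPS20.1 at 1.24 ± 0.13 in vtc2 and 1.46 ± 0.12 in the double mutant (camera adjusted p = 0.394, 0.108 and 0.108). STOMAGEN, which promotes stomata, fell in vtc2 (-1.28 ± 0.22) and the double mutant (-0.70 ± 0.20), and the auxin gene IAA18 fell in all 3 mutants (-0.63 ± 0.10, -0.56 ± 0.10 and -0.68 ± 0.10). Between comparisons that share no arrays, abi4-102 against Col-0 and the double mutant against vtc2 had 220 calls in the same direction (132 higher and 88 lower) and 35 opposite. Independent lists would give 26 higher, 22 lower and 47.9 opposite. For vtc2 against Col-0 and the double mutant against abi4-102 these were 444 higher, 383 lower and 53 opposite, where independent lists would give 89.2, 84.1 and 173.3. Correlations across probe sets, 0.246 and 0.478, lay inside the ranges of simulated unchanged groups (-0.456 to 0.486 and -0.38 to 0.517). Covariances, 0.0213 and 0.052, lay above the simulated ranges (-0.0118 to 0.0131 and -0.0106 to 0.0136).

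Divisions of the arrays into other groups show how often mixed groups gave as many calls as the real ones. Against Col-0, the real groups gave the highest count of all divisions, with 4238 for abi4-102 (highest other 2039 of 35 divisions), 5583 for vtc2 (2688 of 35) and 6879 for the double mutant (834 of 84). The double mutant gave 515 against vtc2 (highest other 158 of 100) and 1412 against abi4-102 (78 of 100). The overlap of the single mutants was 3109 (highest other 3066 of 100, median of the others 0). In all these results 1 division, the real one, gave as many. For the interaction (2109, highest other 3082) and the reversal of vtc2 calls (126, highest other 1724) 2 of 100 divisions gave as many, the real one included. Mixed groups hold the difference between genotypes inside them, which widens their spread and lowers their counts (median 0 in each result). A higher count of the real groups is therefore weak evidence. The divisions against Col-0 and those for the overlap, the interaction and the reversal mixed Col-0 arrays with mutant arrays. They cannot tell a change of a mutant, a shared change, an interaction or a reversal from Col-0 standing apart.

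Calls of the double mutant against vtc2 gathered among neighbouring loci. The fullest window of 100 named loci held 12 calls, on chromosome 1, more than random placement gave (shuffled 95th percentile 9, permutation test of 10000 shuffles, p = 0.0014), and 11 with adjacent called loci counted once (same permutation test, p = 0.0035), which argues against runs of related genes. For most calls of that window the values argue against blocks of parental DNA. Of its calls 16.7% split the parents likewise by at least 0.5 of the change, beside 70.9% of the calls outside it. Smaller differences of the same sign were not counted. Chromosome 4 held the fewest, 0.8% of its named loci against 2.3% elsewhere (Fisher's exact test, adjusted p = 2.02e-05). DNA around VTC2 shared with the vtc2 parent would give this, though shares also differed between chromosomes against Col-0. DNA around ABI4 from the other parent would give more calls on chromosome 2, where no excess was seen (1.8% against 2.1% elsewhere, odds ratio 0.86, adjusted p = 0.58, same test). Its counterpart against abi4-102, more calls on chromosome 4, was seen (8.3% against 5.0% elsewhere). No marker of the parental DNA itself was analysed here.

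Calls of the double mutant against abi4-102 gathered as well, with 18 in the fullest window, on chromosome 4, more than random placement gave (shuffled 95th percentile 16, permutation test, p = 0.0086), and 15 with adjacent loci counted once (same permutation test, p = 0.0547), which leaves runs of related genes open. Of its calls 88.9% split the parents likewise and of those outside it 76.6% (Fisher's exact test, p = 0.272), and as both changes share the abi4-102 arrays, blocks of parental DNA stay open too. On chromosome 2, which carries ABI4, 3.5% of named loci changed and 5.9% elsewhere, as DNA shared with the abi4-102 parent would give. That chromosome also had fewer calls against Col-0 (odds ratios 0.81, 0.83 and 0.84). Yet the fullest window of the double mutant against Col-0, 48 calls, lay on it (permutation test, p = 0.0142). It ran from AT2G39390 to AT2G41120, a stretch that spans the ABI4 locus. With adjacent loci counted once the fullest window of that comparison lay on chromosome 4 (30 calls, permutation test, p = 0.337). In abi4-102 against Col-0, the other comparison of an abi4 mutant with Col-0, the fullest window lay on chromosome 4. It held 33 calls (permutation test, p = 0.0579). These window p-values were not adjusted over the comparisons. An effect of low ascorbate on the genes called against abi4-102 stays open as untested.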
